A study of Mus musculus with 8 samples.

How the data were processed

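Per the labels, RNA came from live mCherry-positive, CD45.2-positive phagocytes sorted from dissociated brains on day 23 after GL261-mCherry-EGFP cells were implanted, and stranded total RNA libraries were made with a kit that removes ribosomal RNA. There were 8 libraries, 2 in each of 4 groups (muMT or WT, isotype IgG or anti-CTLA-4). The values analysed were raw read counts per gene as deposited by the authors, in the layout of STAR's gene count output. Per the submitters' processing notes, adapters were trimmed with cutadapt 5.0 and reads aligned with STAR 2.7 to mm39, and DESeq2 1.42.1 was also named there. The gene annotation behind the counts was not stated. The values were whole numbers that had not been normalized, and reads that map to several places were not counted for any gene.

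The reverse-strand column was used, since its total was 23.3 to 26.5 times that of the forward-strand column in every library. The 4 summary rows at the head of each table (unmapped, multimapping, no gene, ambiguous) were set aside and used only for shares of reads. Reads in genes came to 30516495 and 29466171 in muMT isotype, 31289104 and 30354167 in muMT anti-CTLA-4, 27875336 and 27900880 in WT isotype, and 24784639 and 27014356 in WT anti-CTLA-4. Of 50763 genes listed, 30432 had a read in some library and 16608 passed edgeR's filterByExpr by group. An annotation table of an older mouse assembly (GRCm38.p6) was used only for biotypes, gene spans and positions, and 95.6% of the tested genes matched it by name. A count of 0 over a group was set at 3 reads where a fold was formed. The floors and the 95% intervals cover counting error alone, and since reads copied by PCR are not separate molecules they are narrower than the real uncertainty.

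Counts were scaled by TMM and fitted with edgeR 4.0.16 (R 4.3.3), quasi-likelihood with robust dispersion, as 4 group means over all 8 libraries, which leaves 4 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, with no minimum fold. The 5 comparisons were anti-CTLA-4 against isotype in WT and in muMT, the difference of these effects (WT minus muMT, an interaction contrast), and WT against muMT under each antibody. SE of a log2 fold change is its size over the square root of the F statistic, and SD beside CPM is that of the 2 libraries of a group. The common biological coefficient of variation was 4.11%. Counts of the libraries of a group spread 1.75 to 7.09 times as much as counting error alone (chi-square per degree of freedom), so they were not the same library counted again. The labels do not say if a group's libraries were separate mice. A gene p-value speaks for these libraries, and for mice only if so. With 2 libraries per group no permutation of labels can reach a small p, so none was used. An outlying library could not be tested for.

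Of 41 gene lists written from textbook knowledge, 39 had at least 5 tested members and were tested with camera in limma 3.58.1 on voom values (preset correlation between genes 0.01, Benjamini-Hochberg over the lists). The lists of erythroid cells and of sex-linked genes had too few tested members and were left out. Camera asks whether the members of a list moved up or down relative to all other genes. The same test with the correlation estimated per list, which is stricter, is given beside each list. The test fry asks instead whether the members of a list moved on balance in 1 direction, without other genes as a reference. Ranges of list p over all alternatives include it. Tested members are counted as higher or lower at the threshold over all genes, and changed ones counted again with p adjusted over the list alone. Per comparison the text names the 12 genes higher and the 12 lower with the smallest p among those with adjusted p under 0.05, at least 2-fold change, a mean of at least 5 CPM, a symbol that is not a predicted one and, except for the difference, no overlap between the libraries of the groups. It also names up to 4 members of each described list with the smallest p, and always Ighm, Cd79a, Ctla4, Fcgr1, Fcgr2b, Fcgr3, Fcgr4, Cxcl9, Arg1, H2-Ab1, Itgam and Ptprc. Some genes that these rules would name are not reported here. Ighm had no reads and Cd79a too few to be tested. The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined.

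Tests were run on counts simulated with the measured depths and dispersions, where 200 genes changed, 50 each by 1.25, 1.5, 2 or 4-fold. The WT comparison recovered 22, 38, 42 and 49 in turn, with 17 false calls, and the difference 12, 31, 34 and 47, with 10. In the data 30.5% and 37.3% of genes were called, and error rates there were not tested. The alternatives tried were DESeq2 size factors, no filter on low counts, the unstranded column, the replicate number as a block, a fit without robust dispersion, each library left out in turn, a fit of only the libraries compared, the Wald test of DESeq2 1.42.0, camera with an estimated correlation, fry and, for the agreement between strains, only genes with a mean of at least 5 CPM. Those added after seeing the data were protein-coding genes only, a minimum change of 2-fold and removal of a gene span trend per library. Shares of reads are given in percent without a test.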

Results

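RNA was sequenced from phagocytes sorted out of mouse brains that carried a GL261 glioma. GL261 is a mouse glioma cell line, here marked with mCherry and EGFP, and live CD45.2-positive cells that also carried the tumour's mCherry were collected on day 23 after implantation. The hosts were wild-type C57BL/6 mice (WT) or muMT mice, which lack mature B cells because the membrane exon of the IgM heavy chain is disrupted. Mice received an isotype control IgG or an antibody against CTLA-4, an inhibitory receptor of T cells. The 8 libraries fell into 4 groups of 2: muMT isotype, muMT anti-CTLA-4, WT isotype and WT anti-CTLA-4. Reads assigned to genes per library lay between 24784639 (WT anti-CTLA-4 replicate 1) and 31289104 (muMT anti-CTLA-4 replicate 1). Nothing in the labels says that the 2 libraries of a group came from separate mice, so all p-values measure the spread between these libraries, whatever its source. Libraries of 1 group correlated at r = 0.992 or more across genes on log2 CPM, libraries of different groups at r = 0.982 or less. The first principal component held 44.5% of the variance and the next 23.8%.

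The label of the B cell-deficient strain was checked first. The row of Ighm, the gene disrupted in muMT mice, held 0 reads in all 8 libraries, WT included, as did 16 of the 20 immunoglobulin and T cell receptor constant region rows, so Ighm could not check the label. Jchain, which joins secreted IgM and IgA, had 0 and 2 reads in the muMT isotype and muMT anti-CTLA-4 groups, against 82 and 135 in the WT isotype and WT anti-CTLA-4 groups. With muMT isotype set at 3 reads, Jchain was at least 29.4-fold higher in WT isotype than in muMT isotype. In CPM these Jchain sums were 1.47 (95% Clopper-Pearson interval 1.17 to 1.82) in WT isotype and 2.61 (2.19 to 3.08) in WT anti-CTLA-4. Ms4a1, which encodes CD20, had 3, 6, 9 and 40 reads in muMT isotype, muMT anti-CTLA-4, WT isotype and WT anti-CTLA-4. Cd79a stayed at 6, 5, 11 and 5 reads in the same order.

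The makeup of the reads also differed by group. Uniquely mapped reads that fell in no gene made up 20.6% ± 0.258 (SD, n = 2) in muMT isotype, 18.6% ± 0.0606 in muMT anti-CTLA-4, 29.0% ± 0.804 in WT isotype and 33.2% ± 0.202 in WT anti-CTLA-4. The small non-coding RNAs Rpph1, Rn7sk and Rmrp together took 2.56% ± 0.0669, 1.97% ± 0.0267, 1.47% ± 0.0760 and 0.914% ± 0.0183 of the reads in genes in the same order. Annotated long non-coding RNAs took 1.26% ± 0.0270, 1.13% ± 0.0120, 1.86% ± 0.0503 and 2.41% ± 0.0198, and mitochondrially encoded genes 1.10% ± 0.0117, 0.932% ± 0.00741, 0.919% ± 0.0433 and 0.717% ± 0.0153.

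The first comparison asked how CTLA-4 blockade altered mCherry-positive phagocytes in mice that have B cells. In WT mice, interferon-stimulated genes and inflammatory cytokine genes were higher with anti-CTLA-4, while cell cycle and cholesterol synthesis genes were lower, as were Mrc1 and Chil3, known from alternatively activated macrophages. Nos2, the inducible nitric oxide synthase, rose 5.41-fold, from 86.0 ± 0.178 CPM to 465 ± 12.1 CPM (SD, n = 2, log2 fold change 2.44 ± 0.05 SE, adjusted p = 3.37e-25). Acod1, which makes itaconate, rose 3.96-fold (log2 1.98 ± 0.04, adjusted p = 4.77e-25). Mrc1, the mannose receptor CD206, fell by 1.79 on the log2 scale, from 1532 ± 46.8 CPM to 442 ± 7.41 CPM (adjusted p = 1.16e-24), and Chil3, which encodes the chitinase-like protein Ym1, from 125 ± 0.564 CPM to 30.1 ± 0.608 CPM (log2 -2.05 ± 0.05, adjusted p = 1.55e-23). The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 5069 of 16608 genes, 2435 higher and 2634 lower, and 818 of them changed at least 2-fold (444 higher and 374 lower).

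Further genes that rose most clearly in WT were Clec4d (2.21), Cxcl1 (1.94), Cxcl2 (1.28), Ass1 (1.76), Ly6c2 (2.04), Ly6i (2.14), Pdpn (1.84), Inhba (1.68), Ahnak (1.28) and Rapgef2 (1.26), each with its log2 fold change. Cxcl1 and Cxcl2 attract neutrophils, Ass1 regenerates arginine from citrulline, Ly6c2 marks inflammatory monocytes and Inhba encodes a subunit of activin. Genes that fell most clearly were Igk (-3.85), Ear2 (-3.64), Ccl24 (-2.38), Adamdec1 (-2.69), Npl (-2.0), Dip2c (-1.97), Fkbp5 (-1.78), Tspan13 (-1.72), Spon1 (-1.53) and Ccl8 (-1.31). Ear2 is a ribonuclease of the eosinophil-associated family, Ccl24 is the chemokine eotaxin-2 and Fkbp5 is a glucocorticoid-induced gene. Igk spans the whole kappa light chain locus in the annotation table used here, but the annotation behind the counts was not stated, so it is not known which reads its row counts. It moved with H19 (-4.12) and Krt8 (-3.87), which were singled out after their values were seen, while the B cell markers Ms4a1 and Jchain had more reads in WT anti-CTLA-4 than in WT isotype. By the same rule 115 genes qualified as higher and 118 as lower, and the 12 with the smallest p in each direction are named here and above.

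Interferon-stimulated genes rose together in WT. Of the type I interferon genes, all 39 tested rose (39 adjusted over the list alone), with a median log2 fold change of 0.66 (camera adjusted p = 1.01e-38, 0.00445 with estimated correlation). The members with the smallest p were Rsad2 (1.02), Ifi205 (1.40), Oasl1 (1.08) and Oas3 (1.09). Of the interferon-gamma genes, 30 of 34 tested rose and 1 fell (32 adjusted over the list alone), with a median of 0.80 (camera adjusted p = 2.51e-31, 0.00597 with estimated correlation). Nos2, Acod1, Gbp4 (1.30) and Upp1 (2.58) had the smallest p. Cxcl9, a T cell-attracting chemokine, was the member that fell, at -0.20 ± 0.04 (adjusted p = 0.000597). Of the cytokines and NF-kB targets, 27 of 32 tested rose and 0 fell (30 adjusted over the list alone), with a median of 0.66 (camera adjusted p = 8.01e-31, 0.00445 with estimated correlation), and Cxcl1, Cxcl2, Clec4e (1.44) and Ptgs2 (1.36) had the smallest p. MHC class I presentation genes had 16 of 21 tested higher and 3 lower (21 adjusted over the list alone, adjusted p = 3.38e-08, 0.153 with estimated correlation).

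Proliferation and biosynthesis genes fell in WT. Of the replication-dependent histone genes, all 31 tested fell (31 adjusted over the list alone), with a median of -0.98 (camera adjusted p = 1.02e-30, 0.046 with estimated correlation). H4c3 (-0.92), H4c4 (-0.90), H4c8 (-1.17) and H1f4 (-0.98) were among them. Of the cell cycle genes, 32 of 38 tested fell and 0 rose (34 adjusted over the list alone), with a median of -0.51 (camera adjusted p = 3.47e-15, 0.0203 with estimated correlation), for example Top2a (-0.59), Mcm4 (-0.58), Mcm7 (-0.60) and Mcm3 (-0.53), a topoisomerase and parts of the replicative helicase. Of the genes of cholesterol synthesis and uptake, 21 of 22 tested fell and 0 rose (21 adjusted over the list alone), with a median of -0.60 (camera adjusted p = 5.83e-14, 0.0118 with estimated correlation), including Pmvk (-1.24), Cyp51 (-0.87) and Sqle (-1.16), all enzymes of sterol synthesis. Genes of the unfolded protein response and heat shock had 18 of 26 tested lower and 0 higher (20 adjusted over the list alone, adjusted p = 1.60e-10, 0.046 with estimated correlation). The nuclear-encoded genes of oxidative phosphorylation had 26 of 39 tested lower and 0 higher (33 adjusted over the list alone, adjusted p = 3.24e-08, 0.189 with estimated correlation), and the mitochondrially encoded genes had 8 of 11 tested lower and 0 higher (8 adjusted over the list alone, adjusted p = 1.96e-05, 0.106 with estimated correlation). Beside these shifts, reads assigned to no gene were 33.2% ± 0.202 in WT anti-CTLA-4 and 29.0% ± 0.804 in WT isotype.

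Markers of macrophage types moved apart in WT. Of the monocyte-derived macrophage genes, 13 of 23 tested rose and 5 fell (20 adjusted over the list alone, adjusted p = 0.000249, 0.0519 with estimated correlation), where Ly6c2, Ahnak and Lyz2 (0.93) rose while Chil3 fell. Of the microglia genes, 9 of 20 tested fell and 2 rose (12 adjusted over the list alone, adjusted p = 0.0096, 0.153 with estimated correlation). Lag3 (-0.75), P2ry13 (-0.52), P2ry12 (-0.46) and Tmem119 (-0.40) had the smallest p. Of the border-associated macrophage genes, 8 of 14 tested fell and 2 rose (11 adjusted over the list alone, adjusted p = 0.00233, 0.0944 with estimated correlation). Mrc1, Cd163 (-4.14), F13a1 (-0.67) and Clec10a (-1.23) had the smallest p. The list of alternatively activated and suppressive genes was split, with 12 of 25 tested lower and 9 higher (22 adjusted over the list alone) and no call (camera adjusted p = 0.0629, 0.275 with estimated correlation). Its members Ccl24, Mrc1, Chil3 and Mmp9 (-5.40) fell, whereas Arg1 rose by 0.20 ± 0.04 (adjusted p = 0.000265). The list was called lower without either muMT anti-CTLA-4 library, WT isotype replicate 2 or either WT anti-CTLA-4 library. It was also called in unstranded counts (adjusted p = 0.0331), with the replicate number as a block (0.0478) and by fry, a different test (0.000101). Markers of other cell types shifted too. Of the endothelial genes, 13 of 19 tested rose and 1 fell (16 adjusted over the list alone, adjusted p = 1.20e-07, 0.025 with estimated correlation). Vwf (0.71), Ptprb (0.77), Flt1 (0.52) and Slco1a4 (0.81) had the smallest p. Of the cytotoxic and NK lymphocyte genes, 11 of 23 tested rose and 1 fell (13 adjusted over the list alone, adjusted p = 0.00831, 0.106 with estimated correlation). Of the T cell genes, 7 of 23 tested rose and 1 fell (8 adjusted over the list alone, adjusted p = 0.0437, 0.179 with estimated correlation). Mast cell and basophil genes had 7 of 11 higher and 0 lower (7 adjusted over the list alone, adjusted p = 0.0132, 0.14 with estimated correlation). The T cell call was lost without muMT isotype replicate 1 or 2 or WT isotype replicate 1 (adjusted p = 0.0691, 0.0711 and 0.0895, and adjusted p 0.00379 to 0.179 over all alternatives).

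Among the receptors for IgG, Fcgr1, the high-affinity activating receptor, rose by 0.34 ± 0.05 on the log2 scale (adjusted p = 9.93e-07), while Fcgr2b, the inhibitory receptor, and Fcgr3 fell by 0.40 and 0.45 (adjusted p = 1.24e-09 and 4.72e-10). Fcgr4 was at -0.08 ± 0.04 (adjusted p = 0.202). The neonatal receptor gene Fcgrt fell by 1.14, and the list as a whole had 3 of 7 tested lower and 2 higher (5 adjusted over the list alone, adjusted p = 0.0896, 0.385 with estimated correlation), called in unstranded counts, without a filter and without WT isotype replicate 2 (adjusted p = 0.0388, 0.0208 and 0.0408, and adjusted p 0.0027 to 0.385 over all alternatives). Itgam, which encodes CD11b, rose by 0.62 ± 0.04 (adjusted p = 2.81e-13), Ctla4 fell by 0.66 (adjusted p = 0.000214), H2-Ab1, an MHC class II chain, was at 0.16 ± 0.05 (adjusted p = 0.0069), and Ptprc, which encodes CD45, at -0.08 ± 0.05 (adjusted p = 0.211). The H2-Ab1 call was lost without WT isotype replicate 2 (adjusted p = 0.163) or WT anti-CTLA-4 replicate 2 (adjusted p = 0.106, and adjusted p 4.94e-05 to 0.163 over all alternatives). Of 39 lists tested, 22 were called in WT, 12 up and 10 down, and 8 held with estimated correlation.

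**Figure D1:**
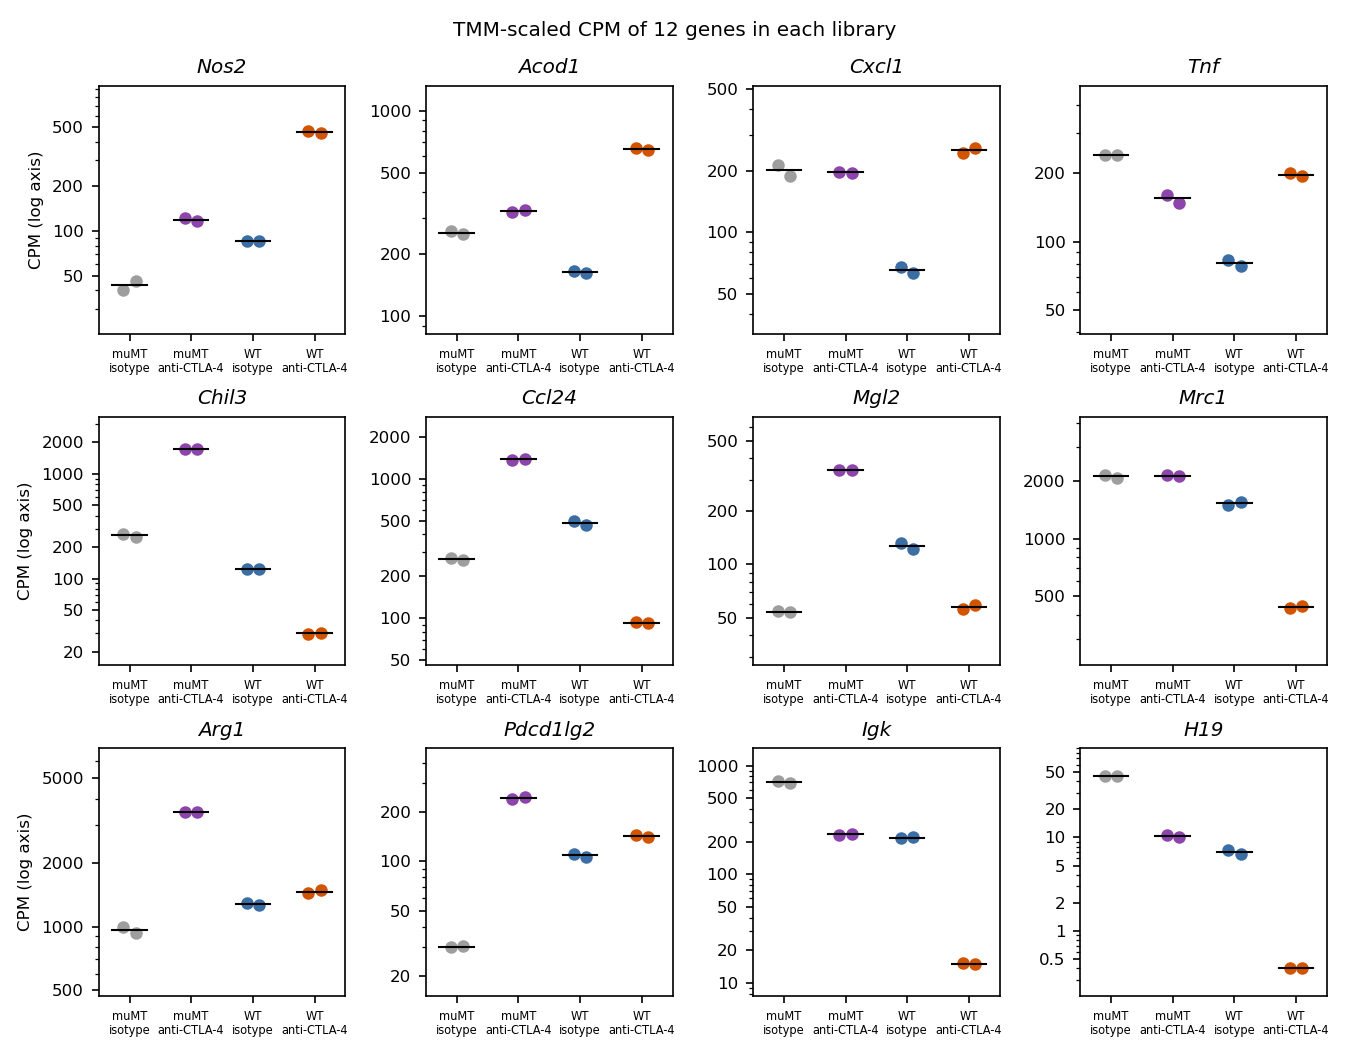
Expression in CPM (counts-per-million, TMM-scaled, log axis) of 12 genes in each of the 8 libraries, with a point per library and a line at the group mean (n = 2). Nos2 and Acod1 were highest in WT anti-CTLA-4, Chil3, Ccl24, Mgl2 and Arg1 were highest in muMT anti-CTLA-4, and Igk and H19 were highest in muMT isotype and lowest in WT anti-CTLA-4.

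The second comparison asked the same in mice without mature B cells. In muMT mice, interferon-gamma genes were higher with anti-CTLA-4, as were Chil3, Arg1 and Pdcd1lg2, and genes of microglia, fibroblasts and mural cells were lower. Chil3 rose 6.69-fold, from 260.2 ± 12.2 CPM to 1741 ± 12.4 CPM (SD, n = 2, log2 2.74 ± 0.05 SE, adjusted p = 4.14e-28). Arg1, which hydrolyses arginine, rose 3.58-fold to 3459.6 ± 14.5 CPM (log2 1.84 ± 0.04, adjusted p = 5.77e-25). Pdcd1lg2, the PD-1 ligand PD-L2, rose 8.04-fold (log2 3.01 ± 0.05, adjusted p = 3.21e-27), and Apoe, the main lipid carrier of the brain, fell by 1.20 on the log2 scale (adjusted p = 4.49e-19). The test called 7063 of 16608 genes, 3678 higher and 3385 lower, 1296 of them by at least 2-fold (333 higher and 963 lower).

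The other genes that rose most clearly were Plet1 (4.22), Inhba (3.46), Apol7c (4.13), Mgl2 (2.65), Ccl24 (2.37), Slc7a2 (1.65), C3 (1.48), Ccl9 (1.5) and Cdh1 (3.54). Those that fell most clearly were Mgp (-3.80), Mcpt1 (-3.70), Adam22 (-3.14), H19 (-2.11), Tgfb3 (-1.73), Igk (-1.60), Col3a1 (-1.54), Col4a1 (-1.49), Fbxo32 (-1.43), Fkbp5 (-1.34) and Vcam1 (-1.02). In all, 115 genes qualified as higher and 184 as lower under the naming rule. Igk and H19 fell here beside markers of brain and connective tissue. Of the fibroblast and mural cell genes, 17 of 18 tested fell and 0 rose (17 adjusted over the list alone, median -1.44, camera adjusted p = 3.21e-16, 0.0257 with estimated correlation). Col3a1 (-1.54), Col4a1 (-1.49), Col1a2 (-1.43) and Col4a2 (-1.45) had the smallest p. Of the oligodendrocyte lineage genes, 11 of 17 tested fell and 2 rose (13 adjusted over the list alone, median -0.94, camera adjusted p = 0.000164, 0.0612 with estimated correlation). Trf (-0.56), Gpr17 (-2.41), Mal (-2.51) and Enpp2 (-0.94) had the smallest p.

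Of the alternatively activated and suppressive genes, 15 of 25 tested rose and 5 fell in muMT (21 adjusted over the list alone, median 0.55, camera adjusted p = 2.37e-07, 0.0612 with estimated correlation). Chil3, Pdcd1lg2, Ccl24 and Mgl2 had the smallest p. Mrc1 stood at 0.01 ± 0.04 (adjusted p = 0.932). Of the interferon-gamma genes, 29 of 34 tested rose and 2 fell (31 adjusted over the list alone, median 0.57, camera adjusted p = 3.21e-16, 0.0257 with estimated correlation). Nos2 (1.47), Serpina3g (1.23), Gbp2 (0.93) and Iigp1 (1.17) had the smallest p. Of the type I interferon genes, 29 of 39 tested rose and 3 fell (32 adjusted over the list alone, median 0.41, camera adjusted p = 3.25e-11, 0.0287 with estimated correlation). Oas1a (0.88), Zbp1 (0.82) and Oas1g (0.92) were among them. MHC class I presentation genes had 17 of 21 tested higher and 1 lower (18 adjusted over the list alone, adjusted p = 3.25e-11, 0.131 with estimated correlation), among them Psme2 (0.86), Psmb10 (0.81), Psmb8 (0.63) and Nlrc5 (0.58). MHC class II presentation genes had 8 of 13 tested higher and 2 lower (10 adjusted over the list alone, adjusted p = 0.00357, 0.276 with estimated correlation), with Ciita (0.81), Ifi30 (0.68), H2-DMb2 (1.03) and H2-DMb1 (0.54) higher. Cytokines and NF-kB targets were split, with 14 of 32 tested higher and 11 lower (25 adjusted over the list alone) and no call (camera adjusted p = 0.228, 0.301 with estimated correlation). Of these, Cxcl3 (1.52), Osm (0.50) and Il6 (0.98) rose, while Tnf fell by 0.64.

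In muMT, nuclear-encoded oxidative phosphorylation, cell cycle, histone and cholesterol genes were called higher, although with estimated correlation none of these 4 calls held. Of the nuclear-encoded genes of oxidative phosphorylation, 33 of 39 tested rose and 0 fell (35 adjusted over the list alone, median 0.34, camera adjusted p = 7.15e-13, 0.149 with estimated correlation). The mitochondrially encoded genes had 2 of 11 tested lower and 0 higher and no call (camera adjusted p = 0.59, 0.743 with estimated correlation). Of the cell cycle genes, 27 of 38 tested rose and 2 fell (29 adjusted over the list alone, median 0.29, camera adjusted p = 5.82e-07, 0.0612 with estimated correlation). Mcm4 (0.63), Mcm2 (0.74), Mcm5 (0.66) and Mcm6 (0.61) were among them. Of the histone genes, 20 of 31 tested rose and 2 fell (24 adjusted over the list alone, adjusted p = 0.000164, 0.301 with estimated correlation). Genes of cholesterol synthesis and uptake had 12 of 22 tested higher and 1 lower (13 adjusted over the list alone, adjusted p = 0.0224, 0.155 with estimated correlation), a call that ended once a trend with gene span was removed, a setting chosen after seeing the data. Of these, Fdps (0.57) rose and Pmvk fell by 0.64. Of the monocyte-derived macrophage genes, 15 of 23 tested rose and 4 fell (19 adjusted over the list alone, median 0.50, camera adjusted p = 2.42e-07, 0.0298 with estimated correlation). Chil3 and F10 (1.53), Ly6c2 (1.59) and Ccr2 (1.25) had the smallest p. Of the microglia genes, 19 of 20 tested fell and 0 rose (19 adjusted over the list alone, median -0.62, camera adjusted p = 5.21e-13, 0.0257 with estimated correlation). Sparc (-0.92), Tmem119 (-0.96), Cx3cr1 (-0.76) and Ccl4 (-0.72) had the smallest p. Mast cell and basophil genes had 9 of 11 tested lower and 0 higher (9 adjusted over the list alone, adjusted p = 0.000808, 0.0798 with estimated correlation). Mcpt4 (-2.85), Kit (-1.20), Tpsb2 (-2.0) and Cpa3 (-1.64) were among them. Endothelial genes had 12 of 19 tested lower and 3 higher (17 adjusted over the list alone, adjusted p = 0.0111, 0.131 with estimated correlation), although Flt1 (1.67) and Pecam1 (0.88) rose, which macrophages can also express, while Ptprb (-1.41) and Slco1a4 (-1.67) fell. Beside these, reads assigned to no gene were 18.6% ± 0.0606 in muMT anti-CTLA-4 and 20.6% ± 0.258 in muMT isotype.

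Fcgr2b rose by 0.36 ± 0.04 on the log2 scale in muMT (adjusted p = 1.14e-08) and Fcgr1 by 0.24 ± 0.05 (adjusted p = 0.000164), while Fcgr3 and Fcgr4 stood at 0.00 ± 0.04 and 0.02 ± 0.04 (adjusted p = 0.984 and 0.708). The list of IgG receptors had 3 of 7 tested higher and 0 lower (3 adjusted over the list alone, adjusted p = 0.24, 0.524 with estimated correlation). Ctla4 fell by 1.32 (adjusted p = 4.14e-09) and Itgam by 0.23 (adjusted p = 2.80e-05). Cxcl9 was at 0.17 ± 0.04 (adjusted p = 0.00303), H2-Ab1 at 0.21 ± 0.05 (adjusted p = 0.000359) and Ptprc at -0.10 ± 0.05 (adjusted p = 0.074). The Cxcl9 call was lost without muMT anti-CTLA-4 replicate 1 (adjusted p = 0.0707, and adjusted p 0.000752 to 0.0707 over all alternatives), and Ptprc passed the threshold without muMT isotype replicate 2 (adjusted p = 0.000467, and adjusted p 0.000467 to 0.919 over all alternatives). Of 39 lists, 18 were called in muMT, 12 up and 6 down, and 5 held with estimated correlation.

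The third comparison asked whether the response to anti-CTLA-4 differed between mice with and without B cells, with the difference given as the WT effect minus the muMT effect. Ccl24, Chil3 and Mgl2, genes of alternatively activated macrophages, fell in WT and rose in muMT. The difference was -4.75 ± 0.07 (SE) on the log2 scale for Ccl24 (adjusted p = 2.06e-30), -4.79 ± 0.07 for Chil3 (adjusted p = 4.10e-30) and -3.79 ± 0.08 for Mgl2 (adjusted p = 2.13e-26). Tnf, Acod1 and Cxcl1, inflammatory genes, had a more positive effect in WT, with differences of 1.92 ± 0.07 for Tnf (adjusted p = 3.58e-19), 1.63 ± 0.06 for Acod1 and 1.97 ± 0.08 for Cxcl1. The interaction test called 6194 of 16608 genes, 2899 with a more positive and 3295 with a more negative effect in WT, 1442 of them by at least 2-fold.

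Other genes with a more positive effect in WT were Mgp (3.03), Il10 (2.02), Clec4d (1.66), Pid1 (1.63), Jag1 (1.63), Arl5c (1.57), Dst (1.35), Nfkbiz (1.22) and Rsad2 (1.20). Il10 encodes an anti-inflammatory cytokine, Jag1 a Notch ligand and Nfkbiz an NF-kB cofactor. Those with a more negative effect were Plet1 (-6.39), Ear2 (-4.62), Apol7c (-4.42), Adamdec1 (-2.85), Pdcd1lg2 (-2.62), Ccl8 (-2.29), Igk (-2.25), F7 (-2.01) and Mrc1 (-1.80). The isotype groups differed as well. Tnf stood at 241 ± 1.15 CPM in muMT isotype, 155 ± 8.82 CPM in muMT anti-CTLA-4, 81.0 ± 3.58 CPM in WT isotype and 197 ± 3.89 CPM in WT anti-CTLA-4, so that its level with anti-CTLA-4 in WT lay below that of muMT isotype. Ccl24 stood at 267 ± 4.59 CPM, 1380.0 ± 7.48 CPM, 486 ± 23.2 CPM and 93.5 ± 1.93 CPM in the same order. Of the fixed genes, the difference was -1.64 ± 0.06 for Arg1 (adjusted p = 9.86e-20), 0.85 ± 0.06 for Itgam (adjusted p = 8.27e-13), -0.76 ± 0.06 for Fcgr2b (adjusted p = 3.39e-12), -0.44 ± 0.06 for Fcgr3 (adjusted p = 4.32e-07) and -0.36 ± 0.06 for Cxcl9 (adjusted p = 2.24e-05). Fcgr1, Fcgr4, H2-Ab1 and Ptprc stood at 0.11, -0.10, -0.05 and 0.02 (adjusted p = 0.227, 0.221, 0.584 and 0.811). Fcgr4 passed the threshold without muMT isotype replicate 1 (adjusted p = 0.0231, and adjusted p 0.0231 to 0.531 over all alternatives). Ctla4 differed by 0.66 ± 0.19 (adjusted p = 0.00803), a call lost without muMT anti-CTLA-4 replicate 2 (0.51, adjusted p = 0.0795) and without WT anti-CTLA-4 replicate 2 (0.48, adjusted p = 0.103, and adjusted p 0.00389 to 0.103 over all alternatives).

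**Figure D2:**
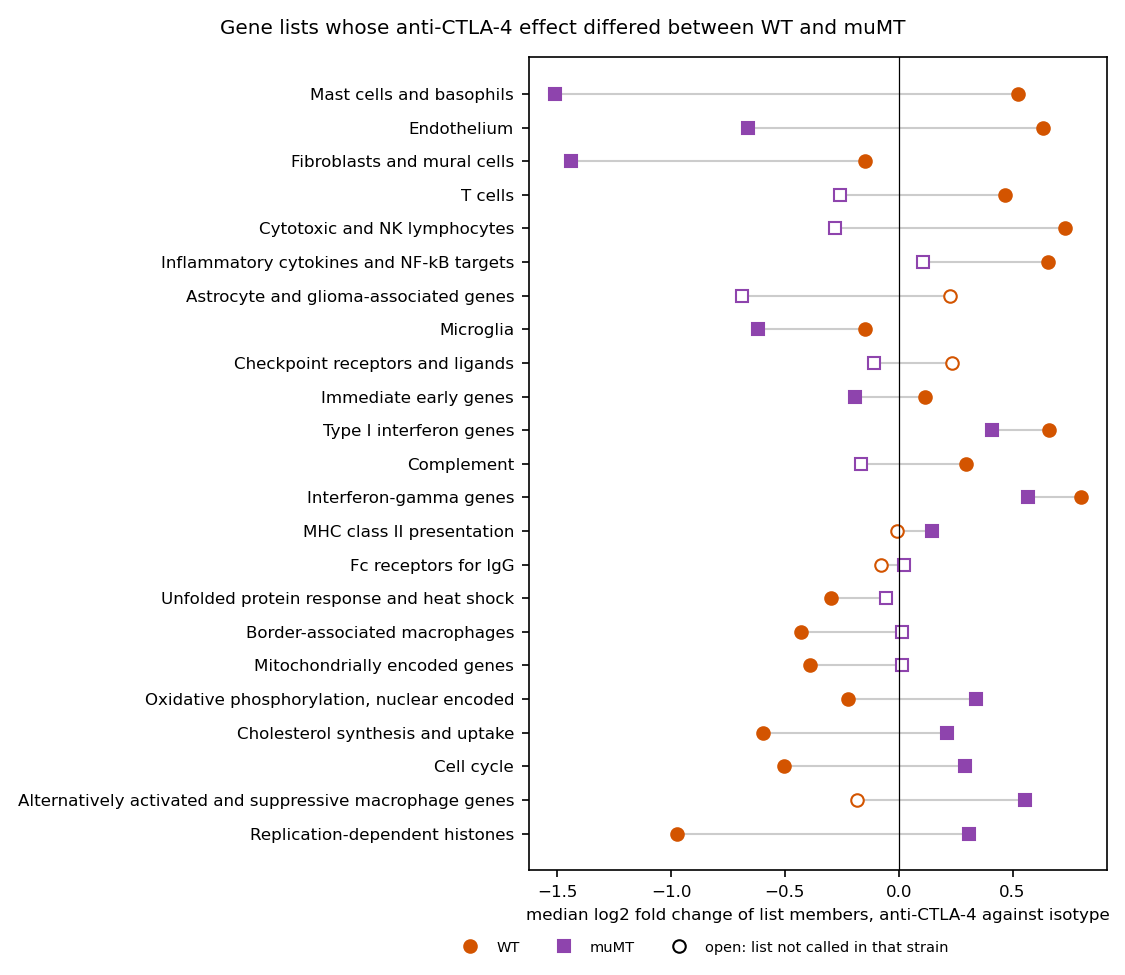
Median log2 fold change of the members of each of the 23 lists called for a difference, anti-CTLA-4 against isotype, with circles for WT and squares for muMT; filled symbols are lists called within that strain. Histone, cell cycle and cholesterol genes lie below 0 in WT and above 0 in muMT, and mast cell and endothelial genes the reverse.

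By list, 23 of 39 had effects that differed between the strains, 13 more positive and 10 more negative in WT, and 9 held with estimated correlation. Cell cycle genes had 31 of 38 members more negative in WT (36 adjusted over the list alone, median difference -0.78, camera adjusted p = 6.12e-18, 0.0244 with estimated correlation). Mcm4 (-1.21), Mcm7 (-1.25), Mcm3 (-1.10) and Mcm6 (-1.04) were among them. Histone genes had 30 of 31 more negative in WT (30 adjusted over the list alone, median -1.29, camera adjusted p = 9.07e-25, 0.0501 with estimated correlation), and cholesterol genes 20 of 22 (21 adjusted over the list alone, median -0.65, camera adjusted p = 7.98e-13, 0.0244 with estimated correlation). Nuclear-encoded oxidative phosphorylation genes had 37 of 39 (37 adjusted over the list alone, median -0.54, camera adjusted p = 1.34e-18, 0.0886 with estimated correlation). These 4 lists were called lower in WT and higher in muMT. With an estimated correlation none of the muMT calls held (adjusted p = 0.0612, 0.301, 0.155 and 0.149 in that order), and in WT that of oxidative phosphorylation was lost (adjusted p = 0.189). Alternative-activation genes had 6 of 25 more positive and 16 more negative (22 adjusted over the list alone, median -0.88, camera adjusted p = 1.25e-08, 0.0394 with estimated correlation). Cytokines and NF-kB targets had 24 of 32 more positive and 3 more negative (27 adjusted over the list alone, median 0.71, camera adjusted p = 3.31e-15, 0.0244 with estimated correlation). Type I interferon genes rose in both strains and more in WT, with 20 of 39 more positive and 2 more negative (23 adjusted over the list alone, adjusted p = 2.22e-06, 0.0394 with estimated correlation). Rsad2, Ifit1 (1.47), Oasl1 (1.02) and Ifit3 (0.92) had the smallest p. For interferon-gamma genes the difference was called as well, with 17 of 34 more positive and 6 more negative (25 adjusted over the list alone, adjusted p = 0.00544, 0.108 with estimated correlation). Microglia genes had 13 of 20 more positive and 1 more negative (15 adjusted over the list alone, adjusted p = 8.40e-07, 0.0394 with estimated correlation). Ccl4 (0.93), Sparc (0.98), Cx3cr1 (0.56) and Golm1 (0.56) had the smallest p.

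Markers of cells outside the phagocyte lineage also differed. Fibroblast and mural cell genes had 15 of 18 more positive and 0 more negative (15 adjusted over the list alone, adjusted p = 5.89e-11, 0.0352 with estimated correlation). Col4a1 (1.35), Col1a2 (1.25), Sparc (0.98) and Col4a2 (1.18) had the smallest p. Endothelial genes had 15 of 19 more positive and 2 more negative (18 adjusted over the list alone, adjusted p = 2.82e-06, 0.0394 with estimated correlation). Mast cell and basophil genes had 8 of 11 more positive and 0 more negative (9 adjusted over the list alone, adjusted p = 2.30e-05, 0.0394 with estimated correlation). The IgG receptor list was called at adjusted p = 0.0295 (adjusted p = 0.298 with estimated correlation), with 0 members more positive and 3 of 7 more negative in WT (3 adjusted over the list alone), and border-associated macrophage genes, with 6 of 14 more negative and 2 more positive (8 adjusted over the list alone), at adjusted p = 0.0316 (adjusted p = 0.144 with estimated correlation). Both calls ended when protein-coding genes alone were fitted, an alternative chosen after seeing the data, and the border-associated call also without WT isotype replicate 2 (adjusted p = 0.0504, and adjusted p 0.000105 to 0.144 over all alternatives).

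Further lists differed between the strains, none of them with estimated correlation (adjusted p 0.0752 to 0.298). T cell genes had 8 of 23 more positive and 0 more negative (9 adjusted over the list alone, adjusted p = 0.00169). Cytotoxic and NK lymphocyte genes had 8 of 23 more positive and 1 more negative (10 adjusted over the list alone, adjusted p = 0.0192). Complement genes had 10 of 19 more positive and 3 more negative (14 adjusted over the list alone, adjusted p = 0.00475). Checkpoint receptors and ligands had 14 of 24 more positive and 2 more negative (16 adjusted over the list alone, adjusted p = 0.00967). Immediate early genes had 14 of 24 more positive and 3 more negative (17 adjusted over the list alone, adjusted p = 0.000961). Astrocyte and glioma-associated genes had 9 of 24 more positive and 2 more negative (11 adjusted over the list alone, adjusted p = 0.00745). Unfolded protein response and heat shock genes had 2 of 26 more positive and 13 more negative (16 adjusted over the list alone, adjusted p = 5.11e-05). MHC class II presentation genes had 2 of 13 more positive and 5 more negative (7 adjusted over the list alone, adjusted p = 0.00938). Mitochondrially encoded genes had 0 of 11 more positive and 7 more negative (7 adjusted over the list alone, adjusted p = 0.00494), a call that ended when a trend with gene span was removed (adjusted p = 0.0516, and adjusted p 0.000369 to 0.173 over all alternatives).

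Across all 16608 tested genes, the effects in WT and muMT, which share no libraries, correlated at r = 0.0977 (Spearman's rho = 0.0635), and at r = 0.163 over genes with a mean of at least 5 CPM; this is a correlation across genes, which are not independent replicates. Over 16 choices of 1 library per group, r lay between 0.0627 and 0.106. Of 2941 genes called in both strains, 1632 (55.5%) moved the same way: 811 rose in both, against 539 expected from independent lists, and 821 fell in both, against 537. Another 817 fell in WT and rose in muMT, against 583 expected, and 492 did the reverse, against 496. Nos2, Ly6c2 and Inhba were among those that rose in both (Nos2 2.44 in WT and 1.47 in muMT, Ly6c2 2.04 and 1.59, Inhba 1.68 and 3.46). Of the 6194 genes whose effect differed by the interaction test, 1309 were called with opposite signs, 576 with the same sign, 1342 in WT alone, 2605 in muMT alone and 362 in neither.

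**Figure D3:**
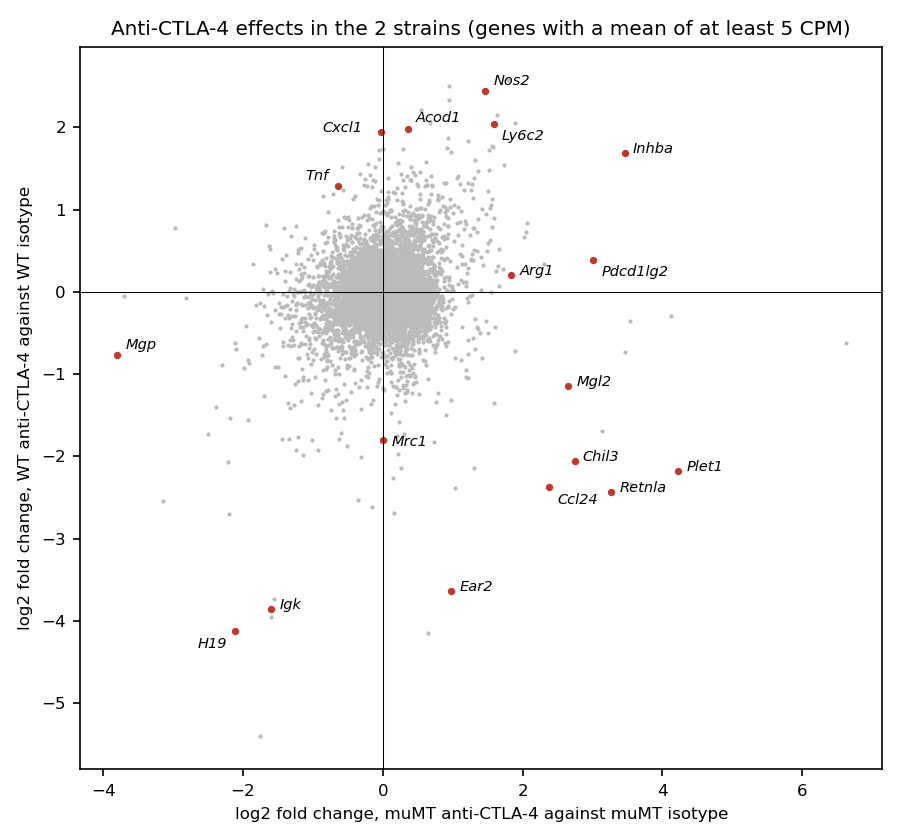
Log2 fold change with anti-CTLA-4 in WT (vertical axis) against that in muMT (horizontal axis), a point per gene for genes with a mean of at least 5 CPM, with genes named in the text in red. Chil3, Ccl24, Mgl2 and Plet1 lie above 0 in muMT and below 0 in WT, and Nos2, Ly6c2 and Inhba above 0 in both.

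The fourth comparison set WT against muMT under the isotype antibody, which asks how phagocytes of the strains differed without blockade. Cxcl9 was higher in WT than in muMT, and Tnf and Cxcl1 were lower. As lists, interferon-gamma genes were called higher and inflammatory cytokine genes lower, but neither call held with estimated correlation (adjusted p = 0.116 and 0.116). Cxcl9 stood at 436 ± 0.613 CPM in WT and 175 ± 2.66 CPM in muMT (SD, n = 2, log2 1.32 ± 0.04 SE, adjusted p = 2.83e-20). Tnf was 2.98-fold lower in WT (log2 -1.58 ± 0.05, adjusted p = 1.56e-20) and Cxcl1 3.06-fold lower (log2 -1.61 ± 0.06, adjusted p = 6.33e-20). Pdcd1lg2 was 3.61-fold higher in WT (log2 1.85 ± 0.06, adjusted p = 3.51e-21). The test called 6504 of 16608 genes, 3312 higher and 3192 lower in WT, 1038 of them by at least 2-fold.

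The remaining genes that were most clearly higher in WT were Apol7c (2.41), Dnase1l3 (1.92), Inhba (1.92), Ncapg2 (1.84), Nnt (1.42), Ccl8 (1.32), Neat1 (1.31), Mgl2 (1.23), C3 (1.19) and Slc7a2 (1.07). Dnase1l3 is a secreted nuclease, Ncapg2 a condensin subunit, Neat1 a nuclear long non-coding RNA and Nnt a mitochondrial transhydrogenase. Those lower in WT were H4c17 (-7.74), H19 (-2.67), Igk (-1.70), Scarna10 (-1.48), Cxcl2 (-1.43), Ccl3 (-1.41), Plk2 (-1.12), Chil3 (-1.06), Klf6 (-1.02) and Ppp1r15a (-1.02). Klf6, Plk2 and Ppp1r15a are stress or early-response genes and Scarna10 is a small Cajal body RNA. H4c17, a histone H4 gene, had 608, 581, 733 and 694 reads in the 4 muMT libraries and 2, 3, 0 and 3 in the 4 WT libraries. Under the naming rule 37 genes qualified as higher and 95 as lower. H19 and Igk were lower in WT beside markers of brain and connective tissue. Of the oligodendrocyte lineage genes, 11 of 17 were lower and 2 higher (13 adjusted over the list alone, median -0.65, camera adjusted p = 0.000934, 0.124 with estimated correlation). Of the fibroblast and mural cell genes, 12 of 18 were lower and 0 higher (12 adjusted over the list alone, adjusted p = 2.81e-07, 0.116 with estimated correlation). Sparc (-0.83), Postn (-2.02), Col4a1 (-0.67) and Col3a1 (-0.60) had the smallest p. Astrocyte and glioma-associated genes had 11 of 24 lower and 2 higher (14 adjusted over the list alone, adjusted p = 0.0499, 0.258 with estimated correlation), a call lost with another scaling (adjusted p = 0.0515), without muMT isotype replicate 2 (adjusted p = 0.0625) or without WT isotype replicate 1 (adjusted p = 0.0871, and adjusted p 0.000166 to 0.258 over all alternatives).

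Of the interferon-gamma genes, 24 of 34 tested were higher and 1 lower in WT (26 adjusted over the list alone, median 0.44, camera adjusted p = 5.66e-12, 0.116 with estimated correlation). Cxcl9, Nos2 (0.99), Iigp1 (0.92) and Serpina3g (0.77) were among them. MHC class I presentation genes followed, where 14 of 21 tested were higher and 1 lower in WT (16 adjusted over the list alone, adjusted p = 3.23e-05, 0.292 with estimated correlation). Of the cytokines and NF-kB targets, 3 of 32 tested were higher and 15 lower in WT (18 adjusted over the list alone, median -0.13, camera adjusted p = 0.000213, 0.116 with estimated correlation). Cxcl2, Tnf, Cxcl1 and Nfkbia (-0.64) had the smallest p. The type I interferon list was called, and 20 of 39 tested were higher and 8 lower in WT (30 adjusted over the list alone, adjusted p = 0.00869, 0.252 with estimated correlation). Of these, Parp14 (0.54) was higher and Oasl1 (-0.84) and Ifit1 (-0.83) lower. Of the histone genes, 21 of 31 tested were higher and 3 lower in WT (25 adjusted over the list alone, adjusted p = 1.30e-06, 0.292 with estimated correlation). Of the cell cycle genes, 17 of 38 tested were higher and 5 lower in WT (24 adjusted over the list alone, adjusted p = 0.00871, 0.268 with estimated correlation). For lipid-associated macrophage genes, 4 of 26 tested were higher and 16 lower in WT (20 adjusted over the list alone, adjusted p = 1.43e-05, 0.124 with estimated correlation). Ctsl (-0.82), Spp1 (-1.01), Csf1 (-0.74) and Lgals3 (-0.47) had the smallest p. Fcgr2b was at 0.31 ± 0.04 (adjusted p = 2.28e-07), Fcgr3 at -0.31 ± 0.04 (adjusted p = 5.80e-07) and Arg1 at 0.40 ± 0.04 (adjusted p = 4.28e-09). Fcgr1, Fcgr4, Ctla4, Itgam and Ptprc did not pass the test, at 0.04, 0.01, 0.00, -0.08 and 0.09 (adjusted p = 0.568, 0.884, 0.998, 0.136 and 0.132), and H2-Ab1 stood at 0.17 ± 0.05 (adjusted p = 0.0037). The H2-Ab1 call was lost without WT isotype replicate 1 (adjusted p = 0.117, and adjusted p 3.37e-05 to 0.117 over all alternatives), while Ptprc passed the threshold without muMT isotype replicate 1 or WT isotype replicate 1 (adjusted p = 0.00079 and 0.0312, and adjusted p 0.00079 to 0.944 over all alternatives), and Itgam in unstranded counts (adjusted p = 0.0212, and adjusted p 0.0212 to 0.34 over all alternatives). Microglia genes had 4 of 20 higher and 9 lower (15 adjusted over the list alone, adjusted p = 0.0182, 0.258 with estimated correlation) in WT. Endothelial genes had 10 of 19 higher and 0 lower (12 adjusted over the list alone, adjusted p = 0.00367, 0.145 with estimated correlation). Lysosome genes had 5 of 33 higher and 15 lower (20 adjusted over the list alone, adjusted p = 0.000934, 0.342 with estimated correlation) in WT. In total 13 of 39 lists were called, 6 up and 7 down, and 0 held with estimated correlation. By fry, 28 lists moved on balance in 1 direction.

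The last comparison set WT against muMT with anti-CTLA-4, the state the treated mice were in. Chil3, Ear2 and Mrc1 were far lower in WT than in muMT, and interferon-stimulated genes were higher. Chil3 was 57.9-fold lower in WT, at 30.1 ± 0.608 CPM against 1741 ± 12.4 CPM (SD, n = 2, log2 -5.86 ± 0.06 SE, adjusted p = 3.54e-35). Ear2 was 39.5-fold lower (log2 -5.31 ± 0.06, adjusted p = 2.19e-32), Mrc1 4.82-fold lower (log2 -2.27 ± 0.04, adjusted p = 1.91e-27) and Nos2 3.89-fold higher (log2 1.96 ± 0.05, adjusted p = 2.89e-23). The test called 9312 of 16608 genes, 4551 higher and 4761 lower in WT, 2210 of them by at least 2-fold.

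Also clearly lower in WT were Plet1 (-6.31), Rnase2a (-5.94), Igk (-3.95), Ccl24 (-3.88), Adamdec1 (-3.32), Mgl2 (-2.57), Ccl6 (-1.95), F7 (-1.76) and Ccl9 (-1.70). Clearly higher were Ptprb (2.81), Neat1 (2.05), Ncapg2 (1.84), Jag1 (1.64), Dusp2 (1.53), Ly6i (1.51), Nfat5 (1.46), Malat1 (1.27), Rapgef2 (1.27), Dst (1.25) and Cpd (1.24). Malat1 and Neat1 are nuclear long non-coding RNAs, which were higher here beside the share of all long non-coding RNAs (2.41% ± 0.0198 in WT and 1.13% ± 0.0120 in muMT). Ptprb is a receptor phosphatase of endothelium, and of the endothelial genes, 17 of 19 tested were higher and 1 lower in WT (18 adjusted over the list alone, median 1.65, camera adjusted p = 2.98e-08, 0.0307 with estimated correlation). Ptprb (2.81), Slco1a4 (2.93), Vwf (1.65) and Tek (3.03) had the smallest p. The naming rule was met by 230 genes higher and 221 lower.

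Of the interferon-gamma genes, 30 of 34 tested were higher and 1 lower in WT (32 adjusted over the list alone, median 0.67, camera adjusted p = 1.11e-15, 0.0307 with estimated correlation). Nos2 (1.96), Gbp4 (1.10), Gbp5 (1.25) and Acod1 (1.00) had the smallest p. Of the type I interferon genes, 31 of 39 tested were higher and 2 lower in WT (33 adjusted over the list alone, median 0.41, camera adjusted p = 1.01e-11, 0.0307 with estimated correlation). Parp14 (1.04), Slfn5 (0.78) and Slfn8 (0.92) were among them. Of the cytokines and NF-kB targets, 23 of 32 tested were higher and 7 lower in WT (30 adjusted over the list alone, adjusted p = 2.95e-06, 0.0307 with estimated correlation). Of the alternative-activation genes, 7 of 25 tested were higher and 16 lower in WT (23 adjusted over the list alone, adjusted p = 3.23e-05, 0.104 with estimated correlation). For oxidative phosphorylation genes, 0 of 39 tested were higher and 38 lower in WT (39 adjusted over the list alone, adjusted p = 1.28e-17, 0.113 with estimated correlation). For cholesterol genes, 0 of 22 tested were higher and 22 lower in WT (22 adjusted over the list alone, adjusted p = 3.01e-10, 0.0307 with estimated correlation). Cyp51 (-1.15), Fdps (-1.19) and Sqle (-1.34) were among them. For cell cycle genes, 1 of 38 tested were higher and 34 lower in WT (35 adjusted over the list alone, adjusted p = 4.34e-12, 0.0307 with estimated correlation), and for histone genes, 0 of 31 tested were higher and 30 lower in WT (30 adjusted over the list alone, adjusted p = 9.26e-14, 0.116 with estimated correlation). Beside these, mitochondrially encoded genes took 0.717% ± 0.0153 of the reads in WT and 0.932% ± 0.00741 in muMT, and 8 of 11 tested members were lower and 0 higher (9 adjusted over the list alone, adjusted p = 0.000657, 0.138 with estimated correlation). Fcgr3 was at -0.75 ± 0.04 (adjusted p = 1.69e-15), Fcgr2b at -0.45 ± 0.04 (adjusted p = 4.89e-11) and Arg1 at -1.24 ± 0.04 (adjusted p = 5.59e-21), while Itgam was at 0.77 ± 0.04 (adjusted p = 7.52e-16), Cxcl9 at 0.95 ± 0.04 (adjusted p = 2.19e-17) and Ctla4 at 0.66 ± 0.15 (adjusted p = 0.00045). Fcgr1, H2-Ab1 and Ptprc, at 0.14, 0.12 and 0.11, were near the threshold (adjusted p = 0.0107, 0.0274 and 0.0393) and lost it in unstranded counts (adjusted p = 0.293, 0.562 and 0.63). Over all alternatives their adjusted p ran from 9.24e-07 to 0.293, from 5.13e-10 to 0.562 and from 1.23e-07 to 0.63. H2-Ab1 and Ptprc also lost it without any 1 of the 4 libraries compared (lowest adjusted p = 0.0892 and 0.143), Ptprc with the replicate number as a block (adjusted p = 0.0605), and Fcgr1 without muMT anti-CTLA-4 replicate 1 or either WT anti-CTLA-4 library (adjusted p = 0.229, 0.0588 and 0.0995). Fcgr4, at -0.09 (adjusted p = 0.0832), passed it in unstranded counts (adjusted p = 0.00137), with only the 4 libraries compared in the fit (adjusted p = 0.000573) and without either muMT isotype library (adjusted p = 0.0192 and 0.0196, and adjusted p 0.000573 to 0.368 over all alternatives). Microglia genes had 12 of 20 higher and 1 lower (14 adjusted over the list alone, adjusted p = 0.00963, 0.138 with estimated correlation) in WT, a call lost in unstranded counts (adjusted p = 0.0793, and adjusted p 0.000248 to 0.138 over all alternatives). Mast cell and basophil genes had 9 of 11 higher and 0 lower (9 adjusted over the list alone, adjusted p = 0.00323, 0.113 with estimated correlation) in WT. Fibroblast and mural cell genes had 11 of 18 higher and 1 lower (12 adjusted over the list alone, adjusted p = 0.0013, 0.116 with estimated correlation). Unfolded protein response and heat shock genes had 4 of 26 higher and 19 lower (23 adjusted over the list alone, adjusted p = 2.90e-07, 0.104 with estimated correlation). The IgG receptor list had 2 of 7 higher and 4 lower (6 adjusted over the list alone, adjusted p = 0.0344, 0.292 with estimated correlation). Border-associated macrophage genes had 4 of 14 higher and 9 lower (14 adjusted over the list alone, adjusted p = 0.0342, 0.158 with estimated correlation). The last 2 calls ended when protein-coding genes alone were fitted (adjusted p = 0.0793 and 0.0608, where adjusted p 0.000344 to 0.292 over all alternatives and adjusted p 2.14e-05 to 0.158 over all alternatives), and the IgG receptor call also when a trend with gene span was removed (adjusted p = 0.132), alternatives chosen after seeing the data. Of 39 lists, 20 were called, 9 up and 11 down, and 6 held with estimated correlation. Members of families of near-identical genes (Ear2 and Rnase2a, Chil3, Ly6c2 and Ly6i, Apol7c, the Oas and Gbp genes, the histones) are uncertain in size, since reads that fit several copies were not counted.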

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

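Effects of anti-CTLA-4 that differed between WT and muMT by the interaction test are listed first, since each was called as a difference between groups. The tests of B cell RNA, of neural and glial RNA and of the mix of monocyte-derived cells and microglia were chosen only after the result was seen. The difference covered 6194 genes and 23 lists. Median log2 differences of the lists, WT minus muMT, were positive for mast cells and basophils (2.04), endothelium (1.37), fibroblasts and mural cells (1.23), T cells (0.91), cytotoxic and NK lymphocytes (0.82), cytokines and NF-kB targets (0.71), astrocyte and glioma-associated genes (0.43), microglia (0.39), checkpoint receptors and ligands (0.31), immediate early genes (0.26), type I interferon genes (0.24), complement (0.23) and interferon-gamma genes (0.23). They were negative for replication-dependent histones (-1.29), alternatively activated and suppressive genes (-0.88), cell cycle (-0.78), cholesterol synthesis and uptake (-0.65), nuclear-encoded oxidative phosphorylation (-0.54), mitochondrially encoded genes (-0.48), border-associated macrophages (-0.24), unfolded protein response and heat shock (-0.14), Fc receptors for IgG (-0.10) and MHC class II presentation (-0.051). With an estimated correlation 9 of these 23 calls held and 14 were lost: T cells (0.0752), cytotoxic and NK lymphocytes (0.108), astrocyte and glioma-associated genes (0.0946), checkpoint receptors and ligands (0.0993), immediate early genes (0.298), complement (0.144), interferon-gamma genes (0.108), MHC class II presentation (0.298), Fc receptors for IgG (0.298), unfolded protein response and heat shock (0.101), border-associated macrophages (0.144), mitochondrially encoded genes (0.173), nuclear-encoded oxidative phosphorylation (0.0886) and replication-dependent histones (0.0501), each with its adjusted p there.

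Of 61 genes named for the effect in either strain or picked by this test itself, 56 differed by it. The log2 difference was positive for Mcpt1 (3.65), Mgp (3.03), Il10 (2.02), Cxcl1 (1.97), Tnf (1.92), Clec4d (1.66), Pid1 (1.63), Jag1 (1.63), Acod1 (1.63), Arl5c (1.57), Col4a1 (1.35), Dst (1.35), Nfkbiz (1.22), Rsad2 (1.20), Rapgef2 (1.06), Nos2 (0.97), Tgfb3 (0.96), Cxcl2 (0.96), Itgam (0.85), Apoe (0.83), Fbxo32 (0.82), Ahnak (0.68), Ctla4 (0.66), Col3a1 (0.63), Pdpn (0.62), Ly6i (0.51), Ly6c2 (0.46) and Ass1 (0.18). It was negative for Plet1 (-6.39), Chil3 (-4.79), Ccl24 (-4.75), Ear2 (-4.62), Apol7c (-4.42), Cdh1 (-3.90), Mgl2 (-3.79), Adamdec1 (-2.85), Pdcd1lg2 (-2.62), Ccl8 (-2.29), Igk (-2.25), Dip2c (-2.18), F7 (-2.01), H19 (-2.0), Mrc1 (-1.80), Inhba (-1.78), Npl (-1.70), Arg1 (-1.64), Slc7a2 (-1.34), Tspan13 (-1.12), Ccl9 (-1.0), Spon1 (-0.97), Fcgr2b (-0.76), C3 (-0.53), Fcgr3 (-0.44), Fkbp5 (-0.44), Cxcl9 (-0.36) and Vcam1 (-0.21). Reads assigned to no gene, which no comparison used, made up 33.2% of uniquely mapped reads in WT anti-CTLA-4, above the 29.0% of its isotype control. Their share moved by -1.95 percentage points with anti-CTLA-4 in muMT, the opposite way in both libraries to that in WT, and this difference was not tested.

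Igk fell with anti-CTLA-4 in WT (log2 -3.85) and in muMT (-1.60) and was lower in WT than in muMT, and 9 genes, itself included, followed its group means (H19, Gm40892, Igk, Gm54221, Krt8, Rfx6, Gpr37, Bcan and Atcay), chosen after their values were seen. RNA of B cells or plasma cells is argued against, because the summed reads of Ms4a1, Jchain and Cd79a were 1.90-fold higher in WT anti-CTLA-4 than in WT isotype (95% interval 1.48 to 2.45) while Igk was 14.6-fold lower, and muMT isotype, without mature B cells, had the most Igk. RNA of tumour, neural or glial cells held by the sorted phagocytes was left undecided (whole cells of these kinds would be removed by the CD45.2 sort). The 31 members of the neural and glial lists under 5 CPM had medians of -0.23 (7 called lower and 6 higher, quartiles -0.58 and 0.53) in WT, -0.87 (15 and 1) in muMT and -0.63 (16 and 2) between the isotype groups, each at or below percentile 0.73 of random lists of the same expression, but 0.00 (6 and 10, quartiles -0.38 and 1.13), at percentile 20.3, between the anti-CTLA-4 groups, where Igk was lower too (log2 -3.95) and which was added after the others were seen. In WT 1 of these 31 (3.23%) fell by 2 or more on the log2 scale. These lists need not hold GL261 genes, so tumour RNA was not tested. The source of the Igk reads stays open, regulation of these genes by strain or treatment included, as does which reads that row counts.

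Many genes changed beside shifts in RNA composition: long non-coding and small RNA shares and reads assigned to no gene differed between the groups. A shift of the scaling by non-coding RNA is argued against as the whole cause, because with protein-coding genes alone in the fit at least 95.9% of the protein-coding calls of each comparison were kept in the same direction. For lists alone a gene length trend is argued against likewise. At least 88.9% of called lists per comparison were kept with it removed. Genes were not retested, and fold changes correlated with gene span (Spearman's rho 0.0669, -0.130, 0.152, 0.0776 and 0.200 in the order of the report). Differences in handling, nuclear content or RNA quality between groups were not tested and stay open, as does a difference between the mice.

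The effect on genes of alternative activation differed between the strains, with a list median of -0.18 in WT and 0.55 in muMT. Camera adjusted p was 0.0629 in WT (split, not called) and 2.37e-07 in muMT (0.275 and 0.0612 with an estimated correlation). In WT it was called without any 1 of 5 libraries, unstranded, with a replicate block or by fry. Another mix of monocyte-derived cells and microglia as the whole cause was left undecided, because the monocyte-derived list without shared members differed by a median of 0.0370 (quartiles -0.11 and 0.41, 8 of 21 more positive in WT and 5 more negative) against -0.88, while microglia genes were more positive in WT (median 0.39, 13 of 20), as such a mix would have it. RNA of eosinophils is argued against in muMT by 1 gene, Siglecf. It held almost all summed reads of Epx, Prg2, Siglecf, Ccr3 and Il5ra. Their summed CPM was 0.938 times as high in muMT anti-CTLA-4 as in muMT isotype (0.535 times in WT). It was at most 28.2 CPM in any library, against at least 3727 CPM for Chil3, Ccl24, Ear2 and Mgl2 in muMT anti-CTLA-4. Epx had 0 reads, Prg2 at most 4 and Il5ra at most 2 per library. Of the eosinophil criteria set beforehand, a marker sum under 10 CPM in every library was not met. The change in muMT alone decided, and that ratio was chosen as the value to give after both were seen. For the mix the criterion used replaced one on signs of list medians that ignored their spread and had argued against it. A phagocyte response that depends on B cells or antibody stays open as a hypothesis, as does any other difference of strain, housing or pooling. Strain and B cells cannot be separated in this design.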

How the results depend on the processing

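A 2-fold minimum, coding genes alone and span trend removal were chosen after the data were seen. Values are in the order WT, muMT, difference, isotype groups and anti-CTLA-4 groups. The 2-fold minimum lowered the genes called to 818, 1296, 1442, 1038 and 2210, by construction. Camera with an estimated correlation called 8, 5, 9, 0 and 6 lists, since it allows for correlated members, and fry, which does not compare with other genes, 28, 32, 35, 28 and 36. The correlation of the effects in WT and muMT was 0.163 with genes of at least 5 CPM and 0.0753 in unstranded counts, and 0.0636 (without muMT anti-CTLA-4 replicate 1) to 0.0974 (without WT anti-CTLA-4 replicate 1) with 1 library left out, and the cause was not tested.

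Other settings kept the numbers of genes called within 1.5 times: 5029, 7057, 6127, 6496 and 9265 with DESeq2 size factors, 4888, 6849, 5970, 6248 and 9081 without a filter, 5510, 7026, 6402, 7239 and 10599 unstranded, 3917, 5706, 4869, 5057 and 7979 by DESeq2's Wald test and 4587, 6601, 5708, 5735 and 7951 with protein-coding genes alone. Fits without robust dispersion (5049, 7055, 6199, 6497 and 9303) or of only the libraries compared (not possible for the difference) also stayed within it. With the replicate number as a block (replicate block) they were 4834, 6830, 5929, 6259 and 9109, although deviations of libraries with the same number correlated at only -0.0415 to 0.0166 between groups, so the numbers are not known to pair them. With each library left out in turn the genes were 3572 to 5791, 5322 to 7092, 5044 to 6273, 4822 to 6242 and 7729 to 9810 and the lists 20 to 24, 18 to 20, 23 to 24, 12 to 16 and 20 to 20, where a lone library was assumed to vary like the other groups. At least 68.2% of the genes called with all libraries were kept in the same direction there. For genes and lists given, no call reversed in any alternative. All 1885 alternative values of the 120 gene results named by the rule kept direction and threshold.

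Over all genes and lists given, 13665 alternative values of genes kept both direction and side of the threshold, 131 lost the call, 41 gained 1 and 51 changed sign without a call. For lists these were 2849, 95, 131 and 45. Lists that lost a call, apart from the estimated correlation, were T cells in WT (DESeq2 size factors, without muMT isotype replicate 1 or 2 or WT isotype replicate 1, coding genes), fibroblasts in WT (without WT isotype replicate 1 or WT anti-CTLA-4 replicate 2, adjusted p = 0.0895 and 0.0732, adjusted p 0.00445 to 0.206 over all alternatives, coding genes), astrocyte genes between the isotype groups (DESeq2 size factors, without muMT isotype replicate 2 or WT isotype replicate 1, coding genes) and immediate early genes (fry in WT and muMT, in muMT also without muMT isotype replicate 2, adjusted p = 0.121, adjusted p 0.000774 to 0.427 over all alternatives). Fc receptors for IgG and border-associated macrophages lost it for the difference and the anti-CTLA-4 groups (coding genes, for the difference in border-associated macrophages also without WT isotype replicate 2), Fc receptors also with the span trend removed, as did mitochondrially encoded genes for the difference and chemokines and cholesterol genes in muMT. Checkpoint receptors and microglia lost it for the anti-CTLA-4 groups in unstranded counts. Depth limits genes with few reads: B cell genes had few reads, and the intervals of ratios formed from them cover counting error alone.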

Other observations

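Genes of hypoxia and glycolysis had 11 of 31 tested higher and 4 lower with anti-CTLA-4 in WT (16 adjusted over the list alone, adjusted p = 0.000897, 0.22 with estimated correlation). Ddit4 (-1.26), Hk2 (0.50), Vegfa (0.49) and Pfkp (0.50) had the smallest p. Complement genes had 10 of 19 tested higher and 5 lower in WT (15 adjusted over the list alone, adjusted p = 0.0101, 0.179 with estimated correlation), and 11 of 19 tested higher and 4 lower in WT than in muMT with anti-CTLA-4 (15 adjusted over the list alone, adjusted p = 0.00564, 0.157 with estimated correlation). Lysosome genes had 16 of 33 tested lower and 4 higher in WT (23 adjusted over the list alone, adjusted p = 0.000897, 0.257 with estimated correlation), and 18 of 33 tested lower and 5 higher in WT than in muMT with anti-CTLA-4 (23 adjusted over the list alone, adjusted p = 0.00208, 0.292 with estimated correlation). Immediate early genes had 12 of 24 tested higher and 4 lower in WT (17 adjusted over the list alone, adjusted p = 0.00725, 0.385 with estimated correlation), and 14 of 24 tested lower and 6 higher in muMT (21 adjusted over the list alone, adjusted p = 0.0192, 0.427 with estimated correlation), where the call was lost without muMT isotype replicate 2 (adjusted p = 0.121, adjusted p 0.000774 to 0.427 over all alternatives). Fibroblast and mural cell genes had 8 of 18 tested lower and 1 higher in WT (11 adjusted over the list alone, adjusted p = 0.0437, 0.206 with estimated correlation), a call lost without WT isotype replicate 1 or WT anti-CTLA-4 replicate 2 (adjusted p = 0.0895 and 0.0732, adjusted p 0.00445 to 0.206 over all alternatives).

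In muMT, CCL chemokines and receptors had 12 of 23 tested higher and 7 lower (21 adjusted over the list alone, adjusted p = 0.00682, 0.255 with estimated correlation), a call lost with the gene span trend removed, a setting chosen after seeing the data (adjusted p = 0.0641, adjusted p 3.50e-05 to 0.255 over all alternatives). Ccl24 (2.37), Ccl9 (1.5), Ccl6 (1.27) and Ccl17 (3.13) had the smallest p. Conventional dendritic cell genes had 11 of 23 tested higher and 4 lower in muMT (16 adjusted over the list alone, adjusted p = 0.00549, 0.149 with estimated correlation). Of these, Naaa (1.39), Ccl17 (3.13), Cadm1 (-1.35) and Irf4 (1.01) had the smallest p. Checkpoint receptors and ligands had 14 of 24 tested higher and 3 lower in WT than in muMT with anti-CTLA-4 (18 adjusted over the list alone, adjusted p = 0.017, 0.126 with estimated correlation), a call lost in unstranded counts (adjusted p = 0.107, adjusted p 4.38e-06 to 0.126 over all alternatives). Lipid-associated macrophage genes had 16 of 26 tested lower and 9 higher in the same comparison (25 adjusted over the list alone, adjusted p = 0.00536, 0.138 with estimated correlation).

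Camera called 8 lists in none of the 5 comparisons. Given where their p was smallest, these were B cells between the anti-CTLA-4 groups (5 of 14 tested higher and 3 lower, 8 adjusted over the list alone, adjusted p = 0.176), efferocytosis and scavenger receptors in muMT (5 of 22 tested higher and 11 lower, 17 adjusted over the list alone, adjusted p = 0.212) and Fc receptor signalling and engulfment machinery in muMT (13 of 28 tested higher and 4 lower, 18 adjusted over the list alone, adjusted p = 0.0807). Next came neurons in muMT (1 of 8 tested higher and 3 lower, 4 adjusted over the list alone, adjusted p = 0.188), neutrophils in WT (3 of 20 tested higher and 9 lower, 14 adjusted over the list alone, adjusted p = 0.0935) and plasma cells and immunoglobulin constant regions in muMT (2 of 7 tested higher and 0 lower, 2 adjusted over the list alone, adjusted p = 0.108). The others were plasmacytoid dendritic cells in muMT (0 of 10 tested higher and 2 lower, 2 adjusted over the list alone, adjusted p = 0.107) and regulatory T cells in muMT (2 of 11 tested higher and 6 lower, 8 adjusted over the list alone, adjusted p = 0.109). Without a filter on low counts engulfment machinery, regulatory T cells, neutrophils and B cells were called there (adjusted p = 0.00598, 0.0209, 0.018 and 0.0246). Engulfment machinery was also called in unstranded counts, with the span trend removed (chosen after seeing the data) and without either isotype library of muMT or WT (adjusted p = 0.0424, 8.14e-05, 0.0466, 0.0333, 0.0482 and 0.0494, adjusted p 8.14e-05 to 0.255 over all alternatives) and regulatory T cells without muMT isotype replicate 2 (adjusted p = 0.0463, adjusted p 0.00461 to 0.276 over all alternatives).

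Between the strains, 433 genes differed at least 2-fold in the same direction under both antibodies. A candidate explanation for part of them is DNA of another strain kept around the disrupted Ighm gene of muMT mice, a test whose criterion was written before its result was seen. Of the 200 tested genes nearest to Ighm, 21 (10.5%) differed at least 2-fold between the isotype groups, against 5.90% elsewhere (ratio 1.78, Fisher's exact p = 0.0102). Between the anti-CTLA-4 groups the ratio was 0.896 (Fisher's exact p = 0.67), so the question was left undecided. Of the 376 of the 433 genes with a position, 9 lay among these 200, so DNA kept there does not account for most of them by position. Ncapg2, which lies near Ighm on chromosome 12, was higher in WT by 1.84 and 1.84 on the log2 scale under isotype IgG and anti-CTLA-4. H4c17, on chromosome 13, stood at -7.74 and -8.59, and Nnt at 1.42 and 0.79.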
